A study of Homo sapiens with 6 samples.

How the data were processed

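Spot intensities came from the scanner software's text files, 1 per array. The intensity values are, per the file headers, single-colour signals of Agilent Feature Extraction 10.7.1.1 on design Agilent-046064, with gProcessedSignal background-subtracted and spatially detrended within the array and no scaling between arrays. The authors' processed table is in log2 units per miRNA. Its processing is not given in the sources used here and was inferred from the values, as columns set to a common distribution with undetected miRNAs at a floor. The 6 columns have a mean of −2.10 and a maximum of 16.55 each, with medians of −3.20, −3.30, −3.23 and −3.32 for parental cytosol, parental mitochondria, resistant cytosol and resistant mitochondria and −3.18 and −3.20 for resistant and parental total RNA. Whether an offset or centring was applied before that step stays unknown, and the table was used only as an alternative. miRNA names are those of the array design.

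Cell line, drug treatment and RNA fraction come from the sample labels and the question from the series description. Per the labels, the mitochondria-enriched fraction is the heavy membrane pellet left after homogenised cells were cleared of nuclei and debris by low-speed spins, and the cytosolic fraction is the supernatant of that pellet. The array positions place 4 arrays on slide 1 (the 3 parental arrays and resistant cytosol) and 2 arrays on slide 2 (resistant mitochondria and resistant total RNA). No slide term was fitted, since with 1 array per group it is separable only in a model without line-by-fraction differences, which are among the questions here. The lines were compared within each fraction, but no paired test over the 3 fractions was made, because the fractions differ by design and the labels do not give them as separate cultures.

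Each array has 62344 spots, of which 60180 carry 4774 probes for 2006 miRNAs, with 4 to 30 spots per probe and 1 to 4 probes per miRNA, and 1000 are negative controls. Spots with the software's outlier flags were left out (2.77% to 4.34% per array), and 0 spots were saturated. The remaining spots were averaged on the linear scale per probe and the probes averaged on the linear scale per miRNA. Each array was scaled to its 75th percentile over the 281 probes detected on all 6 arrays, and log2 was taken. A probe counted as detected where over 50.0% of its spots were flagged gIsWellAboveBG, and a miRNA where at least 1 probe was. The mean of a detected miRNA can thus include probes not above background and lie below the array's lowest above-background probe signal. Differences of such miRNAs rest partly on background signal and are not marked throughout. miRNAs were compared where detected on every array of a comparison, and calls needed a 2-fold difference. The standard error comes from the spread of replicate spots within each array, and the error of a difference combines those of its arrays, with a median of 0.036 to 0.047 per comparison. In every comparison all calls exceeded 2 such errors.

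For miRNAs detected on only 1 side the text gives a bound. The bright side's mean is divided by the dim array's lowest above-background probe signal, or by the miRNA's own mean there if higher. Under the main scaling the fold is then at least the printed one. Another scaling shifts the bounds, and they are given for the main scaling only.

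No p-value is given, since nothing measures the spread between cultures. The 3 fractions of a line were not treated as replicates. List medians are placed among 10000 random lists of the same size matched on mean level in 10 bins, for lists with at least 3 compared members. This percentile is a description across miRNAs, which are not independent.

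Before the data were examined, the following were fixed: the 9 comparisons, the main settings, the 2-fold threshold, the alternatives except for 2, the naming rule and the 18 miRNA lists. The lists, drawn from general knowledge, are miRNAs matching the mitochondrial genome, miRNAs reported in mitochondrial fractions of other cells, let-7, miR-17-92 with paralogs, miR-200, p53-responsive, squamous epithelium, cisplatin response, miR-23-27-24, miR-15/16, miR-30, miR-29, miR-181, the 14q32 cluster, blood cells, fibroblasts and smooth muscle, muscle, liver and neuron, and GC-rich miRNAs often bright on this type of array. A member was looked up by its exact name, or with or without its arm suffix where only 1 such name exists.

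For the comparisons of the lines in 3 fractions, of mitochondrial with total RNA in each line and of the mitochondria-to-total ratio, the rule names up to 10 miRNAs per direction. These have the largest differences among miRNAs with a mean level at or above the median, a difference of at least 2-fold and over 2 spot errors, and the same sign in every probe above background. It adds up to 5 largest bounds per direction and up to 4 members per list with the largest absolute difference. Of these list members the text gives only a part, picked after their values were seen. miR-21-5p and miR-2392 were fixed by name, the latter from knowledge of the study's published work. Mitochondrial against cytosolic RNA is given as counts, list medians and these 2.

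The alternatives fixed in advance were 4 scalings (75th percentile over all probes, median of the miRNAs detected on all arrays, quantile normalization, none), background correction by normexp with an offset of 50, the software's total per miRNA (gTotalGeneSignal), the brightest probe, the software's detection flag, no filter, detection on all 6 arrays and the authors' table. Scaling to the labelling spike-in probes and the sum of the detected probes' gTotalProbeSignal were chosen after seeing the data. Comparisons of cytosolic with total RNA, of the control probe sets, of hairpin arms and of neighbouring genes were also chosen then.

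The code was tested on a pair of simulated arrays, both built from the parental total RNA array, 239 miRNAs compared. Apart from a constant factor between them, their noise came only from replicate spots and negative controls, not from slides or cultures. The counts that follow check the code and do not give the error of real calls. Of simulated differences, 16 of 16 at 3-fold and 17 of 17 at 4-fold were called, 0 of 19 at 1.5-fold and 0 of 187 without a difference. The median estimated folds were 1.50, 2.91 and 3.87. Of 200 random lists 8.50% fell outside percentiles 5 to 95.

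Gene names of a human genome annotation without its sequence matched 1966 of the 2006 miRNAs and 363 of 379 detected on at least 1 array. The annotation served only to find miRNA genes within 10 kb of each other and miRNA genes that overlap small nucleolar RNA genes. Hairpin arms were paired by the arm suffixes of their names. Probe sequences and genome sequence were not used here. The tools were R 4.3.3 with limma 3.58.1 for normexp, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

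Array correlations over the miRNAs detected on both arrays of a pair (194 to 275) were 0.983 for parental cytosol with parental total RNA, 0.968 for resistant cytosol with resistant total RNA, 0.897 between the mitochondrial arrays, 0.913 between the total RNA arrays and 0.925 between the cytosol arrays. Mitochondrial with total RNA stood at 0.677 in the parental and 0.696 in the resistant line. No spot values were shared between arrays.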

Results

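miRNA was measured in CAL-27, an established human tongue squamous carcinoma cell line, and in a cisplatin-resistant line derived from it by culture in cisplatin at concentrations from 1e-07 to 1e-05 M. Total RNA, cytosolic RNA and RNA of a mitochondria-enriched pellet of each line were hybridised to Agilent human miRNA arrays, which gives 6 groups of 1 array each. With 1 array per group no replicate check exists, no test between groups was made, and the number of arrays limits the precision of every value. Each ± is a standard error over replicate spots within arrays and carries no information on differences between cultures. Of 2006 miRNAs on the array, 234, 217 and 293 were detected in parental total, cytosolic and mitochondrial RNA, and 212, 233 and 333 in the resistant line, with 165 detected on all 6 arrays. miR-4454, whose sequence resembles a fragment of a transfer RNA, carried 68.02% of the summed miRNA signal in parental total RNA and 66.27% in resistant total RNA, against 9.81% and 5.44% in the mitochondrial RNA. Differences are log2 and the hsa- prefix of the miRNA names is left out.

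Which miRNAs differ in total RNA between the resistant and the parental line? Both arms of the miR-30a hairpin, miR-100-5p and miR-125b-5p had a higher signal in the resistant line, and miR-100 and miR-125b come from hairpins of the same host transcript. The NF-kB-induced miR-146a-5p was higher too. miR-210, which hypoxia induces, both arms of miR-31 and the epithelial miR-205-5p had a lower signal. Here and in the later comparisons the miRNAs ranked by size are those at or above the median level, and some dimmer miRNAs differed by as much.

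miR-30a-3p was higher in the resistant line by 2.50 ± 0.035 (5.67-fold), miR-30a-5p by 2.07 ± 0.016 (4.19-fold), miR-100-5p by 2.03 ± 0.030 (4.08-fold), miR-125b-5p by 1.89 ± 0.042 (3.70-fold) and miR-146a-5p by 1.85 ± 0.031 (3.60-fold). Then came miR-30c-5p (1.53), miR-155-5p (1.48), miR-1246 (1.34), miR-29a-3p (1.22) and miR-4465 (1.08). The opposite side held miR-210 at −2.77 ± 0.032 (6.80-fold lower), miR-31-3p at −2.74 ± 0.043 (6.69-fold), miR-31-5p at −2.44 ± 0.031 (5.44-fold) and miR-205-5p at −2.44 ± 0.011 (5.42-fold). miR-27b-3p stood at −1.82, miR-3676-5p at −1.69, miR-5100 at −1.65, miR-378a-3p at −1.63, miR-193b-3p at −1.57 and miR-1973, which matches the mitochondrial genome, at −1.57. miR-1246 had the opposite sign, −0.10, in the scanner software's own total per miRNA. For 20.7% to 25.5% of the detected miRNAs per array, that total includes the total of the previous detected miRNA, as the last part shows. An opposite sign in these totals, here and below, therefore need not mean that a direction is unstable. Among miRNAs detected on only 1 of the 2 arrays, miR-1290 was at least 2.65-fold, miR-4651 1.20-fold, miR-3934-5p 1.05-fold and miR-371a-5p 1.03-fold higher in the resistant line, and miR-205-3p, miR-203a, which acts in keratinocyte differentiation, miR-374b-5p, miR-513a-5p and miR-4306 were at least 5.91-fold, 5.87-fold, 1.97-fold, 1.81-fold and 1.55-fold lower. miR-21-5p, which is abundant in many carcinomas, stood at −0.40 (1.32-fold lower).

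Of 204 miRNAs compared in total RNA, 13 were at least 2-fold higher and 31 at least 2-fold lower in the resistant line, around a median of −0.32. The squamous list had a median of −2.59 over 4 compared members, 0.0 on the percentile scale of random lists of matched signal, its members being miR-210, miR-31-3p, miR-31-5p and miR-205-5p. The miR-23-27-24 list stood at −1.36 (5 members, percentile 2.95), with miR-27b-3p and miR-23b-3p (−1.42) lowest, and the ZEB-repressing miR-200 list at −0.89 (5 members, percentile 5.81), with miR-200a-3p at −1.16 and miR-429 at −1.03. miR-29, a repressor of collagen mRNAs, had a list median of 0.81 (3 members, percentile 97.7). No other scaling turned the sign of these 4 lists. The list matching the mitochondrial genome stood at −0.92 (3 members, percentile 7.82) and the list of miRNAs reported in mitochondria at −0.71 (8 members, percentile 13.6), also with 1 sign under every scaling. The list medians of let-7 (−0.35, percentile 45.5), miR-17-92 (−0.07, percentile 82.2), cisplatin response (−0.29, percentile 74.6), miR-15/16 (−0.23, percentile 54.6), miR-30 (−0.30, percentile 48.2) and GC-rich names (−0.16, percentile 94.6) each turned positive under at least 2 of 5 other scalings. Within these, let-7b-5p (−1.51), let-7c (−1.35) and miR-19a-3p (−1.53) were at least 2-fold lower, and so were the GC-rich miR-5787 (−1.25) and miR-1202 (−1.07). miR-181a-5p (0.68) and miR-181b-5p (0.80) made up the miR-181 list. The p53-induced, 14q32 and blood lists each had 1 compared member, miR-34a-5p (0.46), miR-494 (−0.80) and miR-155-5p, and the fibroblast list and the muscle, liver and neuron list had 0.

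Higher and lower miRNAs numbered 22 and 19 with the 75th percentile taken over all probes, 20 and 22 with the median, 16 and 18 with quantile normalization and 18 and 26 without scaling, and these scalings moved the median of all compared miRNAs by 0.22 to 0.40. The 2 total RNA arrays lie on different slides, so slide and line cannot be separated there.

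Which miRNAs differ between the lines in cytosolic RNA? The miR-30a arms and miR-146a-5p again had a higher signal in resistant cells, and miR-31 and miR-205-5p a lower signal. miR-30 family members repress the autophagy gene BECN1. miR-23a-3p and miR-27a-3p, which share a primary transcript, were lower by similar amounts. miR-1202 and miR-5787, of the GC-rich list, were higher in the resistant cytosol although they were lower in resistant total RNA.

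In cytosolic RNA miR-30a-5p was higher by 2.40 ± 0.023 (5.26-fold), miR-30a-3p by 2.25 ± 0.035 (4.76-fold) and miR-146a-5p by 2.17 ± 0.044 (4.51-fold). miR-30c-5p followed at 1.30 (2.47-fold), miR-1202 at 1.23 (2.34-fold), miR-3960 at 1.20, miR-125b-5p at 1.18, miR-5787 at 1.13, miR-100-5p at 1.1 and miR-29b-3p at 1.1. miR-31-5p stood at −2.15 ± 0.022 (4.44-fold lower), miR-31-3p at −2.13 ± 0.024 (4.39-fold) and miR-205-5p at −1.95 ± 0.013 (3.87-fold). Lower values also held for miR-23a-3p (−1.56), miR-378a-3p (−1.44), miR-27b-3p (−1.42), miR-27a-3p (−1.38), miR-23b-3p (−1.32), miR-193b-3p (−1.16) and miR-1260b (−1.11). miR-34a-5p, a p53 target, was detected in resistant cytosol only, at least 2.89-fold higher, as were miR-193a-3p, miR-3940-5p, miR-4634 and miR-3663-3p, at least 1.41-fold, 1.31-fold, 1.27-fold and 1.19-fold higher. miR-203a and the EGFR-repressing miR-7-5p were detected in parental cytosol only, at least 7.77-fold and 4.88-fold lower in the resistant line, and so were miR-374b-5p, miR-4448 and miR-151a-3p, at least 2.18-fold, 1.98-fold and 1.59-fold lower. miR-21-5p stood at 0.37 (1.29-fold higher) and miR-210 at −0.60.

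Of 202 miRNAs compared in cytosolic RNA, 21 were at least 2-fold higher and 21 at least 2-fold lower in the resistant line. The squamous list had a median of −2.13 (5 members, percentile 0.02), with miR-205-3p at −2.18, and the miR-23-27-24 list −1.38 (5 members, percentile 1.35), all 5 at least 2-fold lower. The miR-29 list stood at 1.07 (3 members, percentile 97.9) and the GC-rich list at 0.52 (24 members, 5 at least 2-fold higher, percentile 99.7), with miR-1915-3p at 1.11. miR-181a-5p (1.23) and miR-181b-5p (0.91) gave the miR-181 list a median of 1.07, and the list reported in mitochondria stood at 0.25 (percentile 67.3). None of these turned sign under another scaling. The let-7 list (−0.64, percentile 3.46) turned positive when the 75th percentile was taken over all probes, and the miR-200 list (−0.58, percentile 14.6) under that scaling and without scaling, with opposite signs between the probes of miR-200a-3p, miR-200b-3p and miR-429. The miR-17-92 (−0.18, percentile 19.7), cisplatin (−0.04, percentile 74.1), miR-15/16 (0.09, percentile 75.2) and miR-30 (−0.13, percentile 19.0) lists also turned under at least 1 scaling, as did miR-1973 (0.15) and miR-4485 (0.12), the 2 compared members of the list matching the mitochondrial genome. miR-494 (−0.22) stood for the 14q32 list and miR-155-5p (0.72) for the blood list, and the p53, fibroblast and muscle, liver and neuron lists had 0 compared members.

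The 2 cytosol arrays share a slide, yet the split depends on scaling, with 78 higher and 6 lower for the 75th percentile over all probes, 13 and 27 for the median, 59 and 6 without scaling and 35 and 13 for spike-in scaling. Other scalings moved the median of all compared miRNAs, 0.039, by −0.16 to 0.76.

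Which miRNAs differ between the lines in mitochondrial RNA? miR-1273g-3p, an Alu-derived miRNA, and miR-30a-5p had the largest higher signal in the resistant pellet. miR-210, miR-205-5p and miR-31-5p were lower there as in total RNA. The 4 compared miRNAs of the list matching the mitochondrial genome had a median difference within 2-fold between the lines in this fraction.

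In the mitochondrial RNA miR-1273g-3p was higher in the resistant line by 2.73 ± 0.018 (6.62-fold) and miR-30a-5p by 2.47 ± 0.031 (5.55-fold). miR-100-5p stood at 2.02 (4.06-fold), miR-146a-5p at 1.56, miR-3687 at 1.53, miR-664b-5p at 1.48, miR-29a-3p at 1.45, miR-155-5p at 1.39, miR-29b-3p at 1.21 and miR-513b at 1.19. miR-210 stood at −2.86 ± 0.030 (7.24-fold lower), miR-5585-3p at −2.39 (5.23-fold), miR-205-5p at −2.23 ± 0.010 (4.69-fold), miR-3135b at −2.18 (4.53-fold) and miR-31-5p at −2.00 (4.01-fold). miR-27b-3p (−1.86), miR-574-5p (−1.80), miR-3676-5p (−1.60), let-7b-5p (−1.44) and miR-1268a (−1.28) completed the lower side. miR-30a-3p, detected in the resistant pellet only, was at least 4.02-fold higher, miR-4659a-3p at least 1.92-fold, miR-10b-3p 1.17-fold, miR-10a-5p 1.16-fold and miR-34a-5p 1.12-fold. miR-205-3p, miR-203a, miR-455-3p, miR-148a-3p and miR-4436a, detected in the parental pellet only, were at least 4.79-fold, 2.62-fold, 2.6-fold, 2.48-fold and 2.15-fold lower. miR-21-5p stood at 0.15. miR-2392, fixed by name in advance from knowledge of the study's published work, was detected in both pellets at −0.66, with its probes in opposite directions.

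Of 275 miRNAs compared in mitochondrial RNA, 19 were at least 2-fold higher and 41 at least 2-fold lower, around a median of −0.26. The squamous list had a median of −2.45 (4 members, percentile 0.0), with miR-31-3p at −2.67, and the miR-23-27-24 list −1.24 (5 members, percentile 0.80), with miR-23b-3p at −1.56, without a change of sign under any scaling. The resistant mean of miR-31-3p (−4.93) lay below the lowest above-background probe signal of that array (−4.59), so the size of its difference rests partly on background signal. The miR-29 list stood at 1.21 (3 members, percentile 99.7), also under every scaling. For miR-30 the median of 1.66 (3 members, percentile 99.9) rests on miR-30a-5p and miR-30c-5p (1.66) against miR-30b-5p (−0.66), and it turned to −0.54 when members without detection were let in. miR-15/16 stood at 0.01 (percentile 56.8) and between 0.08 and 0.70 under other scalings. The miR-200 list (−0.67, percentile 5.94) turned positive without scaling, and the lists of let-7 (−0.27, percentile 23.4), miR-17-92 (−0.02, percentile 61.3), cisplatin response (−0.02, percentile 69.5), GC-rich names (−0.15, percentile 21.8), miRNAs reported in mitochondria (−0.02, percentile 61.0) and the mitochondrial genome (−0.39, percentile 44.8) turned under at least 2, with miR-4485 at −0.51 and miR-1973 at −0.26 in the last. Single members beyond 2-fold were let-7c (−1.23), miR-19a-3p (−1.33), miR-125b-5p (1.99), miR-193b-3p (−1.96), miR-513a-5p (1.1), miR-1469 (1.05) and miR-1972 (−1.29). The parental mean of miR-1469 (−4.14) lay below the lowest above-background probe signal of that array (−3.89). Its 1.05 rests partly on background signal and is not a secure 2-fold difference. In the software's own totals miR-193b-3p (0.45), miR-30c-5p (−1.24) and miR-1469 (−0.83) had the opposite sign. miR-494 stood at 0.50, and the p53, miR-181, fibroblast and muscle, liver and neuron lists had 0 compared members.

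The split was 38 and 17 with the 75th percentile over all probes, 30 and 28 with quantile normalization, 60 and 13 without scaling and 34 and 18 with spike-in scaling, with the median of all compared miRNAs moved by 0.22 to 0.69. As in total RNA, line and slide cannot be separated.

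Which differences between the lines hold in every RNA fraction? Of the 165 miRNAs detected on all 6 arrays, 6 were at least 2-fold higher and 11 at least 2-fold lower in the resistant line in all 3 fractions, and 0 were 2-fold different in all 3 with mixed directions, although miR-1202 and miR-5787 differed beyond 2-fold in opposite directions in total RNA and cytosol. Under other scalings their total RNA differences kept that sign but lay within 2-fold, for miR-1202 under all 5 and for miR-5787 under 3. The 17 of both directions numbered 11 without scaling and with spike-in scaling, 7 with normexp and 40 without a filter. The fractions are not separate repeats. Cytosolic and total RNA correlated at 0.983 in the parental and 0.968 in the resistant line, and line and slide coincide in total and mitochondrial RNA. Averaged over the fractions as a summary, miR-30a-5p was higher by 4.96-fold, miR-146a-5p by 3.63-fold, miR-100-5p by 3.29-fold, miR-125b-5p by 3.21-fold, miR-30c-5p by 2.83-fold and miR-29a-3p by 2.37-fold. miR-31-3p was lower by 5.71-fold, miR-205-5p by 4.62-fold, miR-31-5p by 4.59-fold, miR-27b-3p by 3.25-fold, miR-193b-3p by 2.96-fold and miR-23b-3p by 2.70-fold. The means of miR-31-3p in resistant and miR-30c-5p in parental mitochondria lay below the lowest above-background probe signal, so their average folds rest partly on background signal. miR-378a-3p, from an intron of PPARGC1B, was lower by 2.6-fold, miR-378i by 2.57-fold, miR-23a-3p by 2.54-fold, and miR-27a-3p and let-7b-5p by 2.50-fold. Across the 165 miRNAs, which are not independent replicates, the resistant-against-parental differences correlated at 0.687 between total and cytosolic RNA, 0.702 between total and mitochondrial RNA and 0.538 between cytosolic and mitochondrial RNA.

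**Figure D1:**
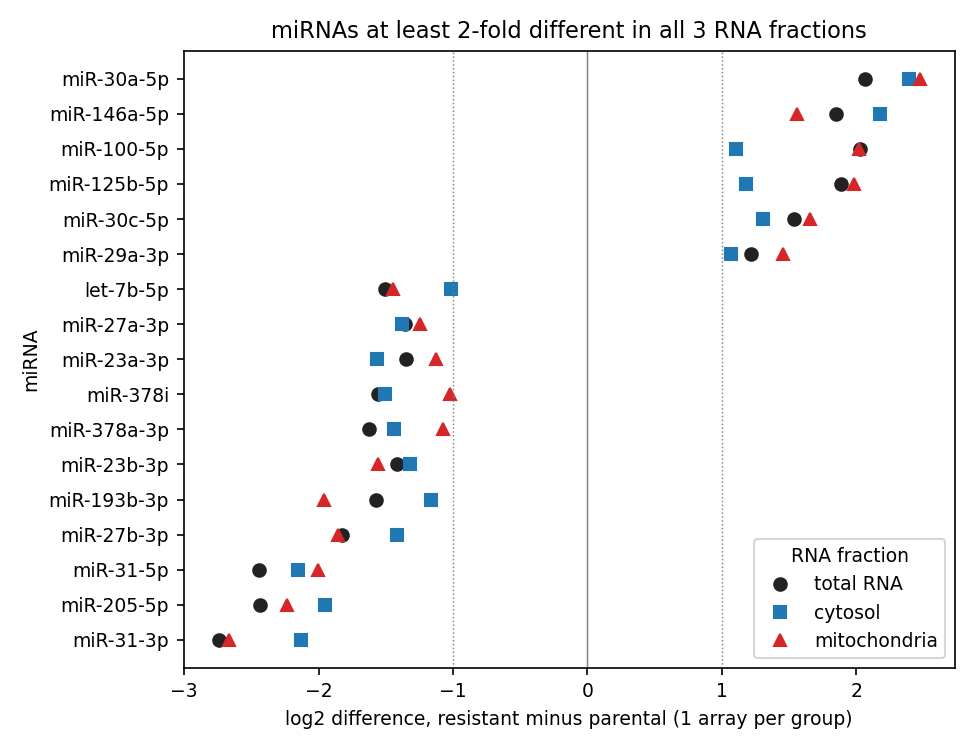
Log2 difference of resistant minus parental signal (horizontal axis) for the 17 miRNAs, one line each, that in the main setting differ at least 2-fold in the same direction in total RNA (black circles), cytosol (blue squares) and mitochondria (red triangles), 1 array per group. Dotted lines mark 2-fold. miR-31-3p runs from −2.74 in total RNA to −2.13 in the cytosol and miR-30a-5p from 2.07 in total RNA to 2.47 in mitochondria.

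Which miRNAs are higher or lower in mitochondrial than in total RNA of the parental line? miR-1973 and miR-4485, which match the mitochondrial genome, were higher in the mitochondrial RNA. The X-linked miR-513a-5p and the GC-rich miR-663a were higher by more. The miRNAs that resemble transfer RNA fragments, miR-1260a, miR-1260b and miR-4454, were the lowest together with miR-5100, and abundant cytoplasmic miRNAs such as miR-21-5p were lower as well.

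In the parental line miR-513a-5p was higher in mitochondrial than in total RNA by 4.33 ± 0.040 (20.2-fold), miR-663a by 4.09 ± 0.076 (17-fold), miR-5006-5p by 3.86 (14.6-fold), miR-574-5p by 2.97 (7.82-fold), miR-4485 by 2.76 (6.76-fold) and miR-1973 by 2.69 ± 0.018 (6.45-fold). miR-1246, which matches a small nuclear RNA, stood at 2.37, miR-3651 at 2.21, miR-4428 at 2.19 and miR-4284 at 2.19. miR-1260b stood at −5.20 ± 0.023 (36.6-fold lower), miR-5100 at −4.79 (27.7-fold), miR-1260a at −4.60 (24.2-fold) and miR-4454 at −4.51 ± 0.011 (22.8-fold). miR-1273g-3p (−3.22), miR-4286 (−3.14), miR-21-5p (−1.83), miR-93-5p (−1.67), miR-30a-5p (−1.67) and miR-3676-5p (−1.63) followed. Detected in the pellet only were miR-4298, miR-6510-5p, miR-4455, miR-4800-5p and miR-630, at least 7.34-fold, 7.11-fold, 6.20-fold, 6.11-fold and 6.01-fold higher. Detected in total RNA only were miR-361-5p, miR-30a-3p, miR-30d-5p, miR-342-3p and miR-224-5p, at least 1.88-fold, 1.84-fold, 1.79-fold, 1.67-fold and 1.63-fold lower in the pellet. In the software's own totals miR-4286 (4.89) had the opposite sign.

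Of 198 miRNAs compared, 49 were at least 2-fold higher and 72 at least 2-fold lower in the parental pellet, against 28 and 92 with the 75th percentile over all probes, and other scalings moved the median of −0.27 by −0.56 to 0.06. No scaling turned the sign of any list named here other than miR-494 (0.20), the only compared 14q32 member. The list matching the mitochondrial genome had a median of 2.69 (3 members, percentile 99.0), with miR-4484 at 2.25, and the list reported in mitochondria 1.53 (9 members, 5 at least 2-fold higher, percentile 99.2), with miR-1275 at 2.02. The GC-rich list stood at 0.95 (25 members, 10 at least 2-fold higher, percentile 99.6), led by miR-4532 (1.97), miR-1268a (1.89), miR-3196 (1.79) and miR-638 (1.53). The conserved families lay on the other side, at −1.67 for miR-30 (3 members, percentile 1.16), −1.44 for miR-200 (5 members, percentile 3.21), −1.23 for miR-17-92 (10 members, percentile 4.21), −1.22 for miR-29 (3 members, percentile 18.9), −1.11 for miR-23-27-24 (5 members, percentile 19.8), −1.02 for miR-15/16 (3 members, percentile 50.4) and −0.97 for let-7 (9 members, percentile 50). Their low members included miR-200a-3p (−2.15), miR-30c-5p (−1.67), miR-19a-3p (−1.53), miR-29b-3p (−1.48), miR-23a-3p (−1.42) and let-7e-5p (−1.08). The squamous list stood at −1.30 (6 members, percentile 2.17), with miR-203a at −1.56, and the cisplatin list at −1.28 (10 members, percentile 1.46). miR-155-5p, alone in the blood list, stood at −1.11. In the software's own totals miR-200a-3p (1.62), miR-30c-5p (1.05) and miR-4532 (−2.57) had the opposite sign.

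Which miRNAs are higher or lower in mitochondrial than in total RNA of the resistant line? miR-5006-5p and the mitochondrial-genome matches miR-1973 and miR-4485 were higher in the pellet, and miR-513a-5p and miR-663a were detected in the pellet but not in total RNA. The same transfer RNA-like miRNAs were, with miR-5100, the lowest. The oncogenic miR-17-92 family and the epithelial miR-200 family were again lower in the pellet, under every scaling.

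In the resistant line miR-5006-5p was higher in mitochondrial than in total RNA by 5.22 ± 0.041 (37.2-fold), miR-1973 by 3.99 ± 0.020 (15.9-fold), miR-4485 by 3.17 (9.01-fold) and miR-3196 by 3.0 (8.02-fold). miR-4284 (2.89), miR-5787 (2.82), miR-1225-5p (2.58), miR-4428 (2.53), miR-638 (2.50) and miR-1275 (2.15) followed. miR-1260b stood at −5.01 ± 0.031 (32.2-fold lower), miR-5100 at −4.90 (29.9-fold), miR-1260a at −4.84 (28.7-fold) and miR-4454 at −4.84 (28.6-fold). Then came miR-93-5p (−1.99), miR-22-3p (−1.64), miR-30c-5p (−1.54), miR-141-3p (−1.44), miR-100-5p (−1.44), miR-30a-3p (−1.38) and miR-21-5p (−1.28, 2.43-fold lower). miR-513a-5p, miR-663a, miR-513b, miR-3687 and miR-513c-5p, detected in the pellet only, were at least 78.3-fold, 29.5-fold, 16.6-fold, 13.3-fold and 12.4-fold higher. miR-30d-5p, miR-342-3p, miR-1181, miR-374a-5p and miR-193a-3p, detected in total RNA only, were at least 2.37-fold, 1.93-fold, 1.83-fold, 1.80-fold and 1.67-fold lower in the pellet.

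Of 194 miRNAs compared in the resistant line, 43 were at least 2-fold higher and 67 at least 2-fold lower in the pellet. The median of the list matching the mitochondrial genome was 3.17 (3 members, percentile 99.7), with miR-4484 at 2.75, that of the list reported in mitochondria 1.30 (8 members, percentile 95.9) and that of the GC-rich list 0.80 (24 members, 7 at least 2-fold higher, percentile 98.2). The mean of miR-4484 in total RNA lay below the lowest above-background probe signal of that array, so its 2.75 rests partly on background signal. All 11 compared members of miR-17-92 were at least 2-fold lower (median −1.19, percentile 0.69), as were 10 of 11 of the cisplatin list (−1.18, percentile 2.24) and all 3 of miR-30 (−1.47, percentile 2.78). Medians stood at −1.19 for miR-23-27-24 (percentile 6.12), −1.11 for miR-200 (percentile 15.2), −0.99 for miR-29 (percentile 39.5), −0.98 for the squamous list (percentile 21.7), −0.94 for let-7 (percentile 35.1) and −0.93 for miR-15/16 (percentile 29.7). No scaling turned the sign of these lists. Members named by size were miR-200a-3p (−1.78), miR-31-3p (−1.38), miR-193b-3p (−1.21), miR-155-5p (−1.20), miR-181a-5p (−1.07) and miR-181b-5p (−0.83). The pellet means of miR-200a-3p and miR-31-3p lay below the lowest above-background probe signal of that array. miR-494, of the 14q32 list, was higher by 1.50 (2.82-fold), while miR-34a-5p, of the p53 list, stood at 0.07 and turned under 3 scalings. In the software's own totals miR-200a-3p (2.21), miR-31-3p (0.34) and miR-193b-3p (1.19) had the opposite sign.

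The resistant split, 39.1% higher in the main setting, was 19.8% higher with the 75th percentile over all probes, 31 and 89 with the median, 33 and 96 with quantile normalization, 56 and 14 without scaling and 53 and 28 with spike-in scaling. Other scalings moved the median of all compared miRNAs, −0.65, by −0.54 to 0.46.

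Across 172 miRNAs compared in both lines, which are not independent replicates, the mitochondria-against-total differences of the lines correlated at 0.918. At least 2-fold higher in both were 33 miRNAs and at least 2-fold lower in both 50, with 0 in opposite directions, where independent lines of these counts would share 9.06 and 21.9. miR-1973, miR-4485, miR-5006-5p and miR-1275 belong to the higher set, and miR-1260b, miR-4454, miR-93-5p and miR-30c-5p to the lower set.

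**Figure D2:**
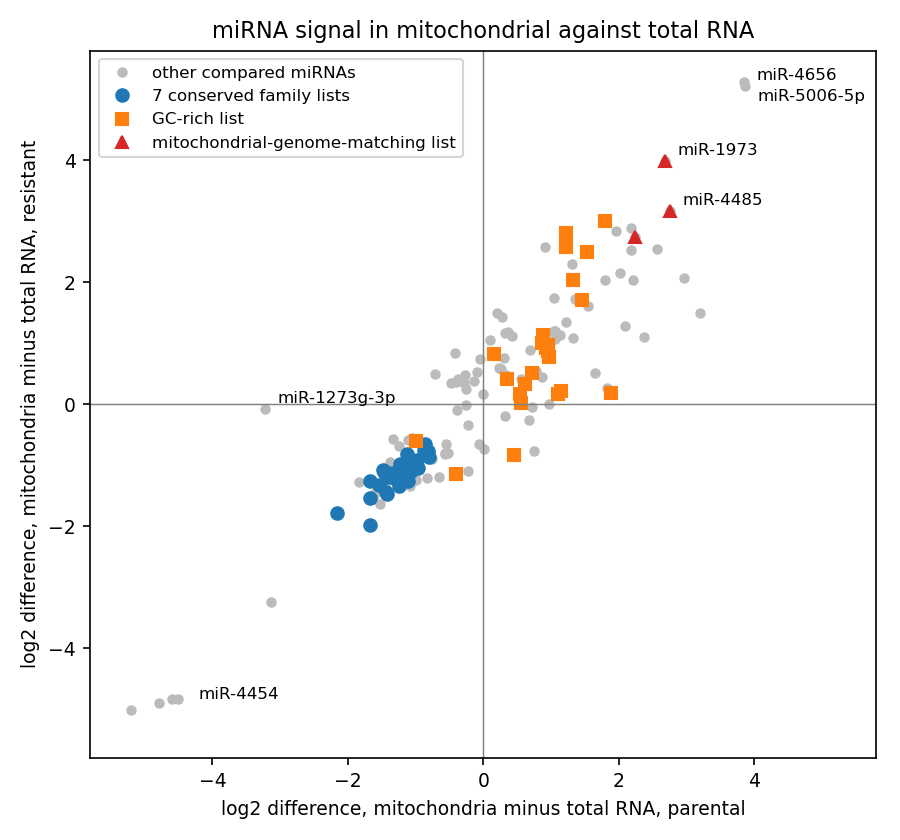
Log2 difference of mitochondrial minus total RNA signal in the parental line (horizontal axis) and the resistant line (vertical axis), 1 point per miRNA compared in both lines (172). Blue circles are members of 7 conserved family lists, orange squares the GC-rich list, red triangles the list matching the mitochondrial genome and grey circles all others, the position of every family list keeping its sign under each scaling. miR-1973 lies at 2.69 and 3.99 and miR-4454 at −4.51 and −4.84. hsa-miR-4656 (3.86 and 5.28) was picked for a label after its values were seen.

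How does mitochondrial RNA compare with cytosolic RNA? In the parental line 48 of 181 compared miRNAs were at least 2-fold higher and 71 at least 2-fold lower in the pellet (34 and 84 with the 75th percentile over all probes, 57 and 42 without scaling), and in the resistant line 46 of 211 were higher and 69 lower (25 and 112 with the 75th percentile over all probes, 38 and 89 with quantile normalization, 62 and 41 without scaling). miR-21-5p stood at −1.67 (3.19-fold lower) in the parental and −1.89 (3.71-fold lower) in the resistant pellet. miR-2392 was higher in the resistant pellet than in the resistant cytosol by 1.35 ± 0.085 (2.55-fold), with −0.37 in the software's own totals. Its mean in the resistant cytosol (−4.72) lay below the lowest above-background probe signal of that array (−4.36). Not all of its probes there were above background, so the size of this difference rests partly on background signal. In the parental line it was detected in the pellet and not in the cytosol. miR-1973 and miR-4485, the compared members of the list matching the mitochondrial genome, gave medians of 5.14 in the parental and 4.62 in the resistant line, and the list reported in mitochondria 1.67 (percentile 99.0) and 1.54 (percentile 99.4). The GC-rich list stood at 1.16 (percentile 99.4) in the parental line and at 0.26 (percentile 92.7) in the resistant line, where it turned negative with the 75th percentile over all probes. The squamous list stood at −1.25 (percentile 2.0) and −1.75 (percentile 1.20), with 1 sign under every scaling. Lower in both lines under every scaling were miR-30 (−1.53 parental, −1.45 resistant), miR-200 (−1.21, −1.34), miR-17-92 (−1.16, −0.93), miR-29 (−1.15, −0.85), miR-23-27-24 (−1.14, −1.14), miR-15/16 (−1.06, −1.08), let-7 (−1.0, −0.99) and the cisplatin list (−1.24, −1.03). The 2 resistant arrays of this contrast lie on different slides.

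Does the mitochondrial share of a miRNA differ between the lines? miR-1273g-3p had the largest higher mitochondria-to-total ratio in the resistant line. The mitochondrial-genome match miR-1973 was also higher against total RNA but lower, by less than 2-fold, against cytosol. miR-1268a, miR-4465 and miR-1246 were lower against total RNA. For miR-1273g-3p the ratio was higher by 3.14 ± 0.026 (8.81-fold), for miR-5787 by 1.59 (3.02-fold), for miR-1225-5p by 1.36, for miR-5006-5p by 1.35, for miR-1973 by 1.30 ± 0.027 (2.47-fold), for miR-494 by 1.30, for miR-5739 by 1.21 and for miR-3196 by 1.21. miR-1268a stood at −1.70 (3.25-fold lower), miR-4465 at −1.51 (2.85-fold), miR-762 at −1.30 and miR-1246 at −1.26 (2.40-fold), while in the software's own totals miR-1246 stood at 0.009. miR-21-5p stood at 0.55 (1.46-fold higher). Of 172 miRNAs 12 were at least 2-fold higher and 7 lower, against 8 and 17 with the median, 9 and 12 with quantile normalization, 34 and 4 without scaling and 22 and 6 with spike-in scaling. The list matching the mitochondrial genome (miR-4484 at 0.50, miR-4485 at 0.41) had a median of 0.50 (percentile 87.5) and the list reported in mitochondria 0.35 (percentile 98.2), each positive under every scaling. The value of miR-4484 rests partly on background signal in resistant total RNA. For the mitochondria-to-cytosol ratio these 2 lists stood at −0.52 and −0.41, negative under every scaling, with miR-1973 and miR-4485, the compared members of the first, both lower by less than 2-fold. The GC-rich list stood at 0.014 (percentile 15.8), and the conserved families and the squamous and cisplatin lists lay between −0.035 (miR-23-27-24) and 0.24 (miR-29), each of them turning under at least 1 other scaling. For the mitochondria-to-cytosol ratio, 6 of 171 were higher and 25 lower (3 and 39 with the 75th percentile over all probes, 10 and 17 with the median, 12 and 21 with quantile normalization), the GC-rich list stood at −0.68 (24 members, percentile 0.39) under a sign that no scaling turned, and miR-21-5p at −0.22. The resistant mitochondrial and cytosol arrays lie on different slides, so a slide effect stays in the mitochondria-to-cytosol ratio. It cancels in the mitochondria-to-total ratio, whose arrays share a slide within each line. Differences between the 2 ratios may therefore come from the slides, and scaling cannot decide this.

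**Figure D3:**
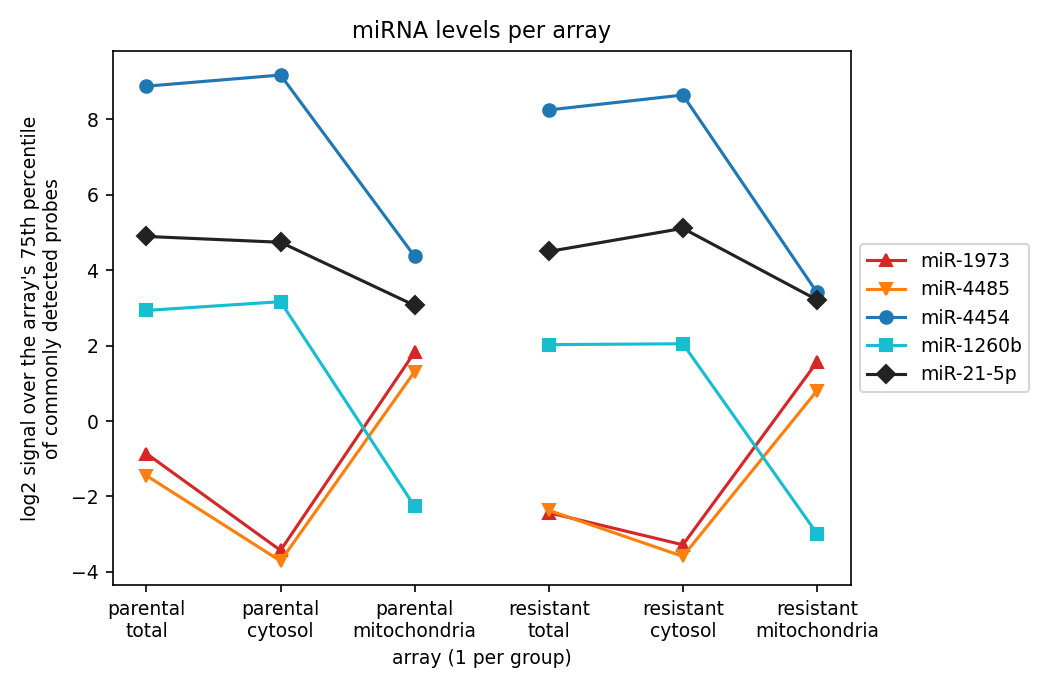
Log2 signal of miR-1973, miR-4485, miR-4454, miR-1260b and miR-21-5p (vertical axis, 0 is the 75th percentile of the commonly detected probes of the array) on each of the 6 arrays, 1 point per array, lines joining the fractions of a cell line. miR-1973 stands at −0.86, −3.43 and 1.83 in parental total, cytosolic and mitochondrial RNA and miR-4454 at 8.88, 9.17 and 4.36.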

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

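All tests weighed in this part were chosen after the results they concern had been seen. After first values, small nucleolar RNA genes with under 3 compared members were counted as undecided.

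Several control probe sets that the files name only by code gave unscaled mitochondrial signal at least 2 times that of total RNA: hur_2 at 2.74 in the parental and 2.10 in the resistant line, hur_4 at 4.10 in the parental line, hur_5 at 4.88 and 2.24, hur_6 at 7.04 in the parental line and mr_1 at 5.91 and 3.19. The rest of this group lay lower, hur_1 at 1.90 and 0.55 and, in the resistant line, hur_4 at 1.97 and hur_6 at 1.29, and the dmr sets lay between 0.56 (dmr_3) and 2.62 (dmr_316, of signal 3.0 to 7.9), both in the resistant line. Between the lines, miR-1202 stood at 1.23 in the cytosol and −1.07 in total RNA. miR-3135b stood at 1.68 in the cytosol and −2.18 in mitochondria. miR-5787 stood at 1.13 in the cytosol and −1.25 in total RNA. The difference between the fractions of these 3 miRNAs was not tested.

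In mitochondrial against total RNA the GC-rich list lay above the members of the 7 conserved family lists by 2.14 (bootstrap SE 0.12, 25 against 38 members) in the parental and 1.90 (SE 0.236, 24 against 40 members) in the resistant line. Dim signals could bring this about. Among the miRNAs whose mean level over both arrays was at or above the median, the gap was 2.20 (SE 0.122) and 1.91 (SE 0.293). A miRNA bright in the pellet but dim in total RNA can pass this filter, so dim total RNA signals are not excluded. The bootstrap SE treats the miRNAs as independent, which they are not. The loss of the single RNA miR-4454 from the pellet could raise all other shares. As 1 common factor this cancels in the gap by construction, so a plain rise of all shares cannot give the gap. That is arithmetic and not a test, since the gap is the pattern itself. Effects of the loss that differ between miRNAs were not tested. Nuclear RNA carried into the pellet may contribute. By the annotation used, which matched 363 of the 379 detected miRNAs, miR-3651 was the only compared miRNA overlapping a small nucleolar RNA gene. It lay 2.47 above the median of all miRNAs in the parental line, and 1 member is too few to decide. miR-664a-5p, miR-664b-3p, miR-664b-5p and miR-1291 also overlap such genes but were detected in pellets only, so the comparison left them out. Detection in the pellet and not in total RNA held for 95 miRNAs in the parental and 139 in the resistant line, so it does not decide either. A difference in the RNA that mitochondria hold and a difference in how GC-rich probes bind in this fraction both stay open.

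The second pattern is the 23 miRNAs at least 2-fold different between the lines in the same direction in both total and mitochondrial RNA, 7 higher and 16 lower, contrasts in which line and slide coincide. A slide effect could produce them, but in cytosol, within 1 slide, all 23 had the same sign, 17 of them beyond 2-fold, with a median of 1.30 (SE 0.12) in that direction. Of all miRNAs compared, 62.4% had the same sign in total RNA and cytosol. That share includes differences of any size, also near 0, so it is not a like-for-like reference for the 23. A scaling by 1 factor per array moves all miRNAs of a contrast the same way, which cannot give both the 7 higher and the 16 lower. A slide may still add to their size, and a culture difference unrelated to resistance stays open with 1 array per line and fraction.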

How the results depend on the processing

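All values in this part come from settings other than the main one, and the causes of their differences were not tested, except where the construction shows them and for the software's total per miRNA. Spike-in scaling and the probe sum were chosen after seeing the data, the others before the data were examined. The direction of the 204 named values of at least 2-fold was kept in all settings except normexp (203), quantile normalization (203) and the software's total per miRNA (190), with detection on all 6 arrays keeping it for all 183 still compared. Scalings by 1 factor per array moved a comparison by at most 0.76, so they could not turn a 2-fold difference. The detection flag, no filter and detection on all 6 arrays use the main values unchanged. A kept direction in these settings was thus fixed in advance. The size was less stable: 2-fold was kept for 180 with the 75th percentile over all probes, 189 with the median, 177 with quantile normalization, 156 without scaling, 172 with spike-in scaling, 111 with normexp, 188 with the probe sum and 179 with the authors' table. The brightest probe kept 197 and the software's detection flag 204. Counts between the lines depend on both the filter and the scaling, and no replicate can say which setting is closest.

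Below, R/P stands for resistant against parental and counts are miRNAs at least 2-fold higher and lower, where the main setting gave 13 and 31 in total RNA, 21 and 21 in cytosol, 19 and 41 in mitochondria (R/P), 49 and 72 in the parental and 43 and 67 in the resistant line for mitochondria against total RNA, 48 and 71 and 46 and 69 for mitochondria against cytosol, 12 and 7 for the R/P mitochondria-to-total ratio, 6 and 25 for the R/P mitochondria-to-cytosol ratio, and 17 for the same direction in all 3 fractions.

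With the 75th percentile over all probes, R/P counts were 22 higher and 19 lower in total RNA, 78 and 6 in cytosol and 38 and 17 in mitochondria. Mitochondria against total RNA gave 28 higher in the parental line and 26 and, to 2 digits, 1.1e2 in the resistant line, against cytosol 25 and 112 in the resistant line, and the mitochondria-to-cytosol ratio 3 and 39. With the median over miRNAs detected on all arrays, R/P gave 20 higher in total RNA and 13 higher in cytosol, 17 lower for the mitochondria-to-total ratio and 10 higher for the mitochondria-to-cytosol ratio. With quantile normalization, R/P gave 18 lower in total RNA and 30 higher in mitochondria, 12 lower for the mitochondria-to-total ratio and 12 higher for the mitochondria-to-cytosol ratio.

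Without scaling, R/P counts were 59 and 6 in cytosol and 60 and 13 in mitochondria, mitochondria against total RNA had 14 lower in the resistant line, mitochondria against cytosol 42 lower in the parental and 41 lower in the resistant line, the mitochondria-to-total ratio 34 and 4, and 11 held in all 3 fractions. With spike-in scaling, R/P counts were 35 and 13 in cytosol and 34 and 18 in mitochondria, mitochondria against total RNA had 28 lower in the resistant line, the mitochondria-to-total ratio 22 higher, and 11 held in all 3 fractions.

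Normexp with an offset of 50 adds a constant that shrinks differences of dim miRNAs by construction. R/P counts were 5 and 12 in total RNA, 5 and 9 in cytosol and 4 and 13 in mitochondria. Mitochondria against total RNA gave 20 and 19 in the parental and 20 and 18 in the resistant line, mitochondria against cytosol 23 and 17 and 20 and 19, the mitochondria-to-total ratio 4 and 4, the mitochondria-to-cytosol ratio 7 lower, and 7 held in all 3 fractions. miR-1469 stood at −0.074 in mitochondria R/P.

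Without a filter, which lets in dimmer miRNAs by construction, R/P counts were 87 and 168 in total RNA, 98 and 267 in cytosol and 94 and 176 in mitochondria. Mitochondria against total RNA gave 232 and 225 in the parental and 178 and 212 in the resistant line, mitochondria against cytosol 205 and 250 and 226 and 184, the mitochondria-to-total ratio 95 and 76, the mitochondria-to-cytosol ratio 112 and 126, and 40 held in all 3 fractions. The miR-30 list stood at −0.54 in mitochondria R/P, and at −0.54 with the software's detection flag too. With detection on all 6 arrays, mitochondria R/P gave 11 and 25 and resistant mitochondria against cytosol 28 higher.

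In the authors' table, R/P gave 22 higher in total RNA and 61 and 66 in mitochondria. Mitochondria against total RNA gave 112 lower in the parental and 129 lower in the resistant line, mitochondria against cytosol 114 and 120 lower, the mitochondria-to-total ratio 29 and 29 and the mitochondria-to-cytosol ratio 31 higher. The miR-30 list stood at −0.16 in mitochondria R/P. With the sum of the detected probes' gTotalProbeSignal, R/P gave 40 lower in cytosol and 66 lower in mitochondria, parental mitochondria against total RNA 74 higher, resistant mitochondria against cytosol 71 higher, the mitochondria-to-total ratio 17 lower and the mitochondria-to-cytosol ratio 14 higher, and the miR-30 list stood at −0.60 in mitochondria R/P.

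The software's total per miRNA (gTotalGeneSignal) includes, for 410 totals over the 6 arrays, the total of the previous detected miRNA, so those totals do not measure their own miRNA alone. With it, the mitochondria-to-total ratio had 18 lower and the mitochondria-to-cytosol ratio 11 higher. Signs opposite to the main setting were found R/P for miR-1246 in total RNA (−0.10) and for miR-193b-3p (0.45), miR-30c-5p (−1.24) and miR-1469 (−0.83) in mitochondria. In mitochondria against total RNA they were found for miR-4286 (4.89), miR-200a-3p (1.62), miR-30c-5p (1.05) and miR-4532 (−2.57) in the parental line and for miR-200a-3p (2.21), miR-31-3p (0.34), miR-193b-3p (1.19) and miR-30b-5p (2.31) in the resistant line. miR-2392 stood at −0.37 in resistant mitochondria against cytosol, and miR-1246 at 0.009 for the mitochondria-to-total ratio.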

Other observations

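All tests in this part were chosen after the data had been seen.

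Cytosolic RNA resembled total RNA closely, a comparison that was not among those fixed before the data were examined. In the parental line 1 of 212 compared miRNAs was at least 2-fold higher and 4 at least 2-fold lower in the cytosol, and in the resistant line 13 and 4 of 206. The mitochondrial-genome matches miR-1973 and miR-4485 had a median of −2.42 in parental and −1.04 in resistant cytosol against total RNA. The GC-rich list stood at −0.25 (percentile 0.26) in the parental and 0.32 (percentile 92.5) in the resistant line. In the parental line let-7 stood at 0.18 (percentile 99.3), and in the resistant line, across slides, miR-17-92 stood at −0.27 (percentile 0.18) and miR-34a-5p, which p53 induces, at 1.27.

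Among the 379 miRNAs detected on at least 1 array, 5 had genes that overlap small nucleolar RNA genes by the annotation used. All 5 were detected in the resistant pellet, but so were 333 of the 379. miR-664a-5p, miR-664b-3p and miR-664b-5p were detected on both mitochondrial arrays and on no other array, miR-1291 on the resistant mitochondrial array only, and miR-3651 stood at 2.21 in the parental and 2.04 in the resistant pellet against total RNA.

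The 2 arms of a hairpin share a precursor, and their resistant-against-parental differences lay 0.28 apart in the median in total RNA (6 pairs) and 0.34 apart in the cytosol (8 pairs), where random pairs lay 0.72 and 0.75 apart (percentiles 5.30 and 3.60). In mitochondrial RNA the arms lay 1.07 apart (6 pairs, percentile 84.7). Both arms had the same sign in 3 of 6 pairs in total RNA, 5 of 8 in the cytosol and 4 of 6 in mitochondrial RNA. The arms thus lay closer than most random pairs in total and cytosolic RNA, but a shared difference of both arms stays undecided in all 3 fractions. The criteria for arms and neighbours were reworded after first values, to ask for all 3 fractions and to leave the miR-17-92 list out of the neighbours.

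Neighbouring miRNA genes within 10 kb, the miR-17-92 list left out, differed by 0.40 in total RNA (27 pairs, percentile 2.20), 0.27 in the cytosol (26 pairs, percentile 0.00) and 0.34 in mitochondrial RNA (23 pairs, percentile 0.50), against 0.70, 0.75 and 0.72 for random pairs. Differences in transcription of shared primary transcripts could produce this, and so could related sequences of neighbours that bind the same probes, which was not tested. A miRNA with several neighbours enters several pairs, while the random pairs were drawn separately. The percentiles may therefore be too extreme.

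The third weighed pattern is the software's total per miRNA, which exceeded the sum of the miRNA's own detected probes by over 1.41-fold for 20.7% to 25.5% of the detected miRNAs per array. It may be a sum carried over from the miRNA before it in the file: for 100% of the 410 cases it equalled, within 2%, the total of the previous detected miRNA plus the sum of its own probes, against 0 to 2 per array in random order. A first version of this test, with the previous miRNA of any name, explained 34.4%. The 410 cases comprise 69, 80, 67, 82, 55 and 57 on the 6 arrays. The other settings of the report do not use this column.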
